A study of Mus musculus with 14 samples.

How the data were processed

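Polyadenylated RNA was sequenced from whole mouse kidney in 14 libraries. The sample labels give a genotype, wild type or transgenic for Smoc2, and a state, untreated kidney (called normal here) or kidney after 7 days of unilateral ureteral obstruction (UUO, the surgical closure of the ureter of one kidney, a model of kidney fibrosis). Libraries were grouped by these labels into 3 wild-type normal, 4 wild-type UUO, 3 transgenic normal and 4 transgenic UUO libraries. A treatment protocol attached to the same samples describes folic acid given to male Balb/c mice, which is not what the genotype, treatment and design labels say, and the groups were taken from the latter. The labels do not say that each library came from its own animal, so the p-values measure the spread between these libraries, which may in part be technical.

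Per the labels' protocols, total RNA was extracted from frozen tissue and libraries were made with a stranded kit that selects messenger RNA. The submitters' processing notes name STAR 2.4.1d, featureCounts 1.4.4 from the Subread package and the mouse genome build mm10, without further settings. The strand setting of the counting and the gene annotation are not given in the sources used here. The deposited files hold raw counts per gene, as whole numbers, with no normalization by the authors and no pooling of libraries. Each file lists 47729 genes by Ensembl identifier. Of these, 47310 matched the GENCODE M21 annotation of build GRCm38 (mm10), which gave symbols and coordinates, and the other 419 held 0.029% of all counts. Because the strand setting is not known, counts of genes that overlap another gene on the opposite strand are uncertain. Near-identical gene copies and pseudogenes are uncertain too, since reads that match several places can be split or lost.

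Total counts ran from 19483994 to 30033405 per library. Genes were kept by edgeR's filterByExpr on the 4 groups, which left 17926 genes. Counts were scaled by trimmed mean of M-values factors, and levels are given in CPM, the usual unit of counts relative to the scaled library size. In R 4.3.3, edgeR 4.0.16 fitted group means to all 14 libraries and tested each comparison with its quasi-likelihood test (glmQLFit and glmQLFTest). Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene is said to have risen, fallen or changed only at an adjusted p under 0.05. Intervals of a log2 fold change cover 95%. Fitting all libraries at once gives every comparison one shared estimate of the spread per gene. For a gene at 0 in every library of a group, the fold is given as a lower bound against a floor of 3 counts over that group, which covers counting error only, since amplified reads without molecular identifiers are not independent molecules.

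There were 5 comparisons: UUO against normal within each genotype label, transgenic against wild type within each state, and the interaction of genotype with UUO. The tests, the named-gene rule, 35 gene lists and the alternatives were fixed before the data were examined. The lists cover kidney cell types, fibrosis, injury, metabolism, immune cells, stress responses, the circadian clock and tissues that could be carried over with the kidney. All but the Y-linked list had at least 3 genes tested, which left 34 lists. Each list was tested against all other genes with camera of limma 3.58.1, with the correlation within the list estimated. The preset correlation of 0.01 was an alternative. The test fry of the same package asked whether the genes of a list move on balance in one direction or, in its mixed form, in either direction, without comparing the list with other genes. Member counts are given over all genes tested and, where stated, adjusted over the list alone.

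The genes that may be named for a comparison were Smoc2, the 8 largest rises and 8 largest falls among changed genes with an established symbol, a mean of at least 3 on the log2 CPM scale in the higher group and no overlap between the libraries compared, and up to 4 members of each list with the smallest p. Where fewer than 20 genes had changed, all could be named.

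The alternatives were median-ratio and upper-quartile scaling, no filter, a filter of at least 50 counts in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, only the libraries of the groups compared, and each library left out in turn. Each library was counted as a sample of its own, as labelled. The pipeline was tested on simulated counts for the real genes, in which 200 genes were changed. All other genes had 1 mean over all libraries, so the simulated counts held no obstruction response. The shares therefore apply where few genes change. They do not give the recovery in the real obstruction comparisons, in which most genes changed. For wild-type UUO against normal it recovered 21% of genes changed 1.5-fold, 65.5% of those changed 2-fold and 81.5% of those changed 4-fold, over 17590, 17592 and 17599 genes. For transgenic UUO against normal the shares were 23%, 56% and 86.5%. Between genotypes they were 15%, 54.5% and 81% in normal kidney and 36.5%, 69% and 87% after UUO. For the interaction they were 1.5%, 48% and 73.5%. No library was left out.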

Results

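The series measured messenger RNA in whole mouse kidney to ask how the kidney responds to 7 days of unilateral ureteral obstruction (UUO) and whether a Smoc2 transgene alters that response. SMOC2 is a secreted calcium-binding matrix protein of the SPARC family. There were 3 wild-type normal, 4 wild-type UUO, 3 transgenic normal and 4 transgenic UUO libraries. Total counts per library were 22104417 to 30033405 in wild-type normal, 20667885 to 26171382 in wild-type UUO, 19483994 to 23994849 in transgenic normal and 21584036 to 27670785 in transgenic UUO kidney. Of the spread over all genes, 75.3% lay on a first principal component that separated UUO from normal libraries. A second component with 4.1% placed all 7 wild-type libraries above 0 and all 7 libraries labelled transgenic below 0. Xist, transcribed from the inactive X chromosome of female cells, was at 780 to 1701 CPM in every library, and the Y-linked genes together had 0 to 2 counts per library. The protocol text that describes male mice therefore differs from the measured levels.

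Smoc2 (ENSMUSG00000023886), at chromosome 17 from 14279506 to 14404790 on mm10, was measured first because it is the gene of the transgene. It was at 25.2 ± 16.1 CPM (SD, n = 3) in wild-type normal kidney and at 21.8 ± 9.66 CPM (SD, n = 3) in normal kidney labelled transgenic. After UUO it was at 147 ± 11.4 CPM (SD, n = 4) in wild type and 96.1 ± 18.5 CPM (SD, n = 4) in the libraries labelled transgenic. The difference of labelled transgenic from wild type was -0.22 on the log2 scale in normal kidney (95% interval -1.05 to 0.61, edgeR adjusted p = 0.850). After UUO it was -0.61 (95% interval -1.29 to 0.07, edgeR adjusted p = 0.389), with all 4 libraries labelled transgenic below all 4 wild-type libraries. The sign in normal kidney rested on single libraries, since the difference was 0.43 without wild-type normal library 3 and 0.11 without transgenic normal library 4. Smoc2 counts therefore show no excess in the libraries labelled transgenic, and every direction between genotypes given here is one between labels.

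**Figure D1:**
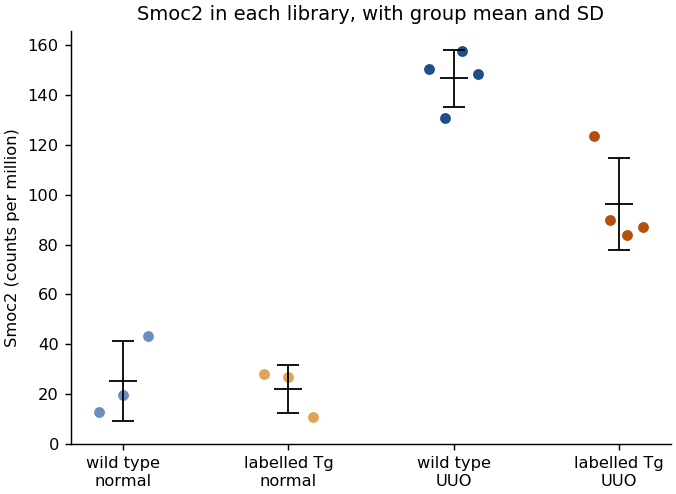
Smoc2 in each of the 14 libraries, in CPM on the vertical axis, for the 4 groups on the horizontal axis. Points are libraries and bars are the group mean and SD. Means rise from 25.2 and 21.8 CPM in normal kidney to 147 and 96.1 CPM after UUO in wild-type and labelled transgenic libraries.

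In wild-type kidney after obstruction, most genes of the matrix, injury and macrophage lists were higher and most genes of the proximal tubule and respiratory chain lists were lower. As whole lists, 0 of 34 passed camera with an estimated correlation, and 6 had an unadjusted p under 0.05. Smoc2 rose 5.80-fold (log2 2.54, SE 0.38, edgeR adjusted p = 4.94e-05), above every normal library in 4 of 4 UUO libraries. Without wild-type normal library 3 its log2 change was 3.19. Spp1, which encodes the secreted matrix protein osteopontin, rose from 2004 ± 201 CPM (n = 3) to 23013 ± 3613 CPM (n = 4) and was the most abundant gene in each UUO library. Egf, a growth factor made in the distal tubule, fell from 2518 ± 53.6 CPM to 114 ± 92.6 CPM (log2 -4.46, SE 0.60, edgeR adjusted p = 1.93e-05). In all, 10950 of 17926 genes tested changed, with 5603 higher and 5347 lower, and 5501 of them changed at least 2-fold.

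Il1f6, which encodes interleukin 36 alpha, had 0 counts in all 3 wild-type normal libraries and was at 18.4 ± 4.83 CPM (SD, n = 4) after UUO, at least 407-fold higher. Arhgap36 reached 25.3 ± 6.07 CPM and the chemokine gene Ccl7 9.38 ± 3.06 CPM, from 0.0130 CPM each, or 1 count over the 3 normal libraries. The keratin gene Krt20 rose to 28.7 CPM, Retnla of alternatively activated macrophages to 21.3 CPM, Fcrls to 56.6 CPM and the neutrophil chemokine gene Cxcl2 to 11.6 CPM, each from under 1 CPM. Lyz1 rose to 17.9 ± 14.2 CPM, with its level uncertain because Lyz2 is a near-identical copy. Pvalb, a calcium buffer of the distal convoluted tubule, fell from 124 to 2.28 CPM. Bhmt of betaine metabolism fell by 5.66, Hpd of tyrosine breakdown by 5.33 and the tryptophan dioxygenase gene Ido2 by 4.73 on the log2 scale. Sec14l3 fell by 4.48 on that scale. Cyp2d12 and Ly6f, members of families of close copies, fell by 5.26 and 5.04 with uncertain counts. Single libraries moved some of these falls by over 1.5-fold. Without wild-type UUO library 2 the log2 change was -6.35 for Pvalb, -6.32 for Bhmt and -5.07 for Sec14l3, and without library 4 it was -6.20 for Hpd, -5.51 for Ido2 and -5.74 for Ly6f.

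Most genes of the matrix and mesenchymal lists were higher in wild-type UUO. None of these lists passed camera with an estimated correlation, whose adjusted p stands beside each count. All 38 extracellular matrix genes were higher (camera adjusted p = 0.171), among them the collagen cross-linking enzyme gene Lox (3.12 to 81.3 CPM, log2 4.68), Mfap4 (log2 4.30), the metalloproteinase gene Mmp14 (log2 3.46) and the protease inhibitor gene Timp1 (0.778 to 86.9 CPM, log2 6.83). Of 20 myofibroblast and mesenchymal genes, 17 rose (camera adjusted p = 0.171), including Vim (log2 2.61) and Tagln (33.3 to 269 CPM, log2 3.01). Of 9 genes of a list of SPARC and SMOC family and follistatin-domain genes, 6 rose and none fell (camera adjusted p = 0.171), with Sparc going from 267 ± 90.9 to 1283 ± 243 CPM. TGF-beta signalling had 16 of 20 genes higher and 1 lower (camera adjusted p = 0.171), with Tgfbi at log2 2.65, and integrin and focal adhesion had 13 of 23 higher and 1 lower (camera adjusted p = 0.383). The counts adjusted over the list alone were the same.

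Most genes of the tubule segment and mitochondrial lists were lower in wild-type UUO. No such list passed camera with an estimated correlation, and its adjusted p is given with each count. Of 37 proximal tubule genes 36 fell (camera adjusted p = 0.171), among them G6pc of glucose production (557 to 26.9 CPM, log2 -4.37, SE 0.35) and Gatm of creatine synthesis (1685 ± 322 to 178 ± 69.7 CPM). Of 31 genes of fatty acid oxidation 30 fell (camera adjusted p = 0.171), with Acadm at log2 -3.32, and all 39 nuclear genes of the respiratory chain fell (camera adjusted p = 0.171), with Ndufs1 at log2 -1.73. All 7 mitochondrially encoded genes tested fell (camera adjusted p = 0.210), with mt-Cytb going from 25927 ± 3239 to 7794 ± 1867 CPM. The loop of Henle and distal tubule list had 17 of 19 genes lower and 1 higher (camera adjusted p = 0.171), with Calb1 at log2 -3.85 and Klk1 at log2 -3.57. The collecting duct list had 14 of 19 lower and 2 higher (camera adjusted p = 0.210). The list of NRF2 and glutathione genes had 18 of 21 lower and 2 higher (camera adjusted p = 0.190), and its member Gpx3, a secreted peroxidase made in the proximal tubule, fell from 28090 to 5520 CPM. Adjusted over the list alone, proximal tubule had 37 lower and collecting duct 15 lower, and the other counts were the same.

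Most genes of the injury list and of most immune lists were higher in wild-type UUO. Camera with an estimated correlation passed none of these lists, at the adjusted p given with each. In the tubular injury list 26 of 27 genes were higher (camera adjusted p = 0.0762), including the hyaluronan receptor gene Cd44 (2.83 to 208 CPM, log2 6.20) and the adhesion gene Vcam1 (11.2 to 656 CPM, log2 5.87). All 28 macrophage and monocyte genes rose (camera adjusted p = 0.0936), with C1qa at 17.8 ± 2.91 CPM in normal and 265 ± 15.4 CPM in UUO kidney. So did 23 of 24 T cell genes (camera adjusted p = 0.195), with Ccl5 at log2 6.31 (7.06 without wild-type normal library 3), and 8 of 9 neutrophil genes (camera adjusted p = 0.171). The chemokine and cytokine list had 29 of 31 genes higher and 1 lower (camera adjusted p = 0.0762), antigen presentation 18 of 20 higher (camera adjusted p = 0.171, with Cd74 at log2 3.56), interferon response 25 of 30 higher (camera adjusted p = 0.364), and B cell and plasma cell genes 9 of 18 higher and 1 lower (camera adjusted p = 0.203). Complement genes were higher in 13 of 20 cases and lower in 2 (camera adjusted p = 0.171), and C3 rose from 27.0 to 1995 CPM. The cell cycle list had 30 of 32 genes higher and 1 lower (camera adjusted p = 0.171), with Cdk1 at log2 3.13. Immediate early and heat shock genes had 16 of 24 higher and 3 lower (camera adjusted p = 0.226), with Egr1 at log2 3.56. The counts adjusted over the list alone differed in that the injury list had 27 higher and the other counts were the same.

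Podocyte genes both rose and fell in wild-type UUO, while the endothelial genes that changed all fell. Camera with an estimated correlation gave adjusted p = 0.229 for clock genes, 0.456 for male-biased genes and 0.601 or more for podocytes, endothelium, endoplasmic reticulum stress, erythroid genes and the tissues that could be carried over. Podocyte genes had 6 of 15 higher, with Nes at log2 1.60, and 5 lower, with Podxl at log2 -0.56. Endothelial genes had 8 of 20 lower and none higher, with Kdr going from 88.0 to 37.0 CPM. Clock genes had 1 of 18 higher and 11 lower, and endoplasmic reticulum stress genes 2 of 21 higher and 7 lower. Among tissues that could be carried over, urothelium had 6 of 11 genes higher, with Krt14 at 16.1 ± 21.5 CPM after UUO (log2 4.69, and 3.16 without wild-type UUO library 1), a call that limma-voom alone did not make (adjusted p = 0.0701, where the alternatives ran from 6.67e-05). Adipose tissue had 1 of 7 higher, adrenal gland 2 of 4 higher and 1 lower, skeletal muscle 3 of 7 higher and 2 lower, and pancreas and spleen 2 of 3 higher and 1 lower. Erythroid genes had 1 of 7 higher and 2 lower, and the fall included Slc4a1, a chloride-bicarbonate exchanger that intercalated cells also make (94.9 to 6.47 CPM). Male-biased kidney genes had 3 of 12 higher and 8 lower, with Kap at log2 -3.58 (-4.17 without wild-type UUO library 2), and no library showed Y-linked expression above 2 counts. Adjusted over the list alone, podocyte genes had 7 higher, stress genes 5 lower, urothelium 5 higher, muscle 3 lower and male-biased genes 9 lower, and the other counts were the same. The muscle list had a median of -0.43 and a mean of 0.05 on the log2 scale, and camera gave it as lower.

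Of the 34 lists in wild-type UUO, 24 passed camera with the preset correlation of 0.01, of which 0 passed with an estimated correlation, and 27 moved on balance in one direction by fry. Upper-quartile scaling moved the median log2 change of all genes from 0.0455 to 0.158, so changes smaller than that shift depend on the scaling.

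In kidney labelled transgenic after obstruction, too, most genes of the matrix, injury and macrophage lists were higher and most genes of the proximal tubule and respiratory chain lists were lower. As whole lists, 0 of 34 passed camera with an estimated correlation, and 8 had an unadjusted p under 0.05. Smoc2 rose 4.43-fold (log2 2.15, SE 0.38, edgeR adjusted p = 1.93e-04), in 4 of 4 UUO libraries above every normal one. The C3 gene rose from 28.2 ± 12.7 to 2745 ± 648 CPM, Cd44 from 2.44 to 155 CPM, and Egf fell from 1927 ± 562 to 55.6 ± 25.3 CPM. In all, 11264 genes changed, with 5817 higher and 5447 lower, and 5836 changed at least 2-fold.

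Il1f6, with 0 counts in all 3 normal libraries, was at 20.1 ± 3.84 CPM (SD, n = 4) after UUO, at least 357-fold higher. Fgb, the fibrinogen beta chain gene, rose to 34.1 ± 11.2 CPM, Arhgap36 to 26.7 ± 1.31 CPM, the neurosecretory gene Vgf to 17.1 ± 9.79 CPM and the stromelysin gene Mmp3 to 14.2 ± 4.95 CPM, from 4 or 5 counts in normal kidney. Cd300lf, a myeloid receptor gene, reached 12.7 CPM and the chemokine gene Ccl12 10.7 CPM, from 3 counts each over the 3 normal libraries. Timp1 rose from 0.874 to 161 CPM (log2 7.58, and 8.62 without transgenic normal library 1). Bhmt fell by 6.72, Pvalb by 6.49, Hpd by 6.11, the sodium-activated potassium channel gene Kcnt1 by 5.89 and the mitochondrial carbonic anhydrase gene Car5a by 5.21 on the log2 scale. Cyp2d12 and Hsd3b5, whose families hold close copies, fell by 5.65 and 5.47 with uncertain counts. The log2 change of Bhmt was -7.34 without transgenic UUO library 3 and that of Pvalb -7.37 without library 1.

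Most genes of the matrix and mesenchymal lists were higher and most genes of the tubule segment and mitochondrial lists lower in the labelled transgenic kidney. At the adjusted p beside each count, none of these lists passed camera with an estimated correlation. By list, all 38 extracellular matrix genes rose in the labelled transgenic kidney (camera adjusted p = 0.174), with Mfap4 at log2 4.94 and Col8a1 going from 6.14 to 103 CPM. Myofibroblast genes had 18 of 20 higher and 1 lower (camera adjusted p = 0.174), with Tagln at log2 3.05. The SPARC, SMOC and follistatin-domain list had 7 of 9 higher (camera adjusted p = 0.174), with Sparc at log2 2.80 and the activin antagonist gene Fst, which is listed for its follistatin domains and belongs to neither family, going from 20.1 ± 5.03 to 76.1 ± 17.4 CPM. TGF-beta signalling had 16 of 20 higher and 1 lower (camera adjusted p = 0.174), with Tgfb1 at log2 2.34, and integrin genes 15 of 23 higher and 1 lower (camera adjusted p = 0.360), with Itga5 at log2 1.92. Proximal tubule genes fell in 35 of 37 cases (camera adjusted p = 0.177), with Ass1 of arginine synthesis at log2 -3.58 and G6pc at log2 -4.69. Fatty acid oxidation genes fell in 30 of 31 cases (camera adjusted p = 0.174), with Acadm at log2 -3.52, and those of the respiratory chain in 39 of 39 (camera adjusted p = 0.174), with Uqcrc1 at log2 -1.77. Mitochondrially encoded genes fell in 7 of 7 cases (camera adjusted p = 0.224), with mt-Co1 at log2 -1.72. The loop and distal list had 17 of 19 lower and 1 higher (camera adjusted p = 0.174), with Calb1 at log2 -4.53 and Klk1 at log2 -3.95, the collecting duct list 15 of 19 lower and 2 higher (camera adjusted p = 0.174), and the NRF2 list 18 of 21 lower and 2 higher (camera adjusted p = 0.194). The counts adjusted over the list alone differed in that TGF-beta had 17 higher, proximal tubule 37 lower and NRF2 19 lower, and the other counts were the same.

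Most genes of the injury and immune lists were higher in the labelled transgenic kidney. By camera with an estimated correlation, 0 of these lists passed, at the adjusted p given with each. Injury genes rose in 26 of 27 cases in the labelled transgenic kidney (camera adjusted p = 0.0967), with Vcam1 at log2 5.50, and macrophage genes in 27 of 28 (camera adjusted p = 0.117), with C1qa at 268 ± 36.2 CPM. T cell genes rose in 21 of 24 cases (camera adjusted p = 0.194), with Ccl5 at log2 5.98, B cell genes in 12 of 18 (camera adjusted p = 0.174) and neutrophil genes in 8 of 9 (camera adjusted p = 0.143). Chemokine genes had 29 of 31 higher and 1 lower (camera adjusted p = 0.0967), complement genes 13 of 20 higher and 3 lower (camera adjusted p = 0.174), interferon genes 25 of 30 higher (camera adjusted p = 0.402), and antigen presentation 18 of 20 higher and 1 lower (camera adjusted p = 0.174), with Cd74 at log2 3.50. Cell cycle genes had 30 of 32 higher and 1 lower (camera adjusted p = 0.174), with Mki67 going from 6.25 to 81.9 CPM, and immediate early genes 16 of 24 higher and 5 lower (camera adjusted p = 0.332). Adjusted over the list alone, T cells had 23 higher and immediate early genes 6 lower, and the other counts were the same.

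Podocyte, endothelial and endoplasmic reticulum stress genes both rose and fell in the labelled transgenic kidney. With an estimated correlation, camera gave adjusted p = 0.391 for clock genes, 0.479 for male-biased genes and 0.566 or more for podocytes, endothelium, endoplasmic reticulum stress, erythroid genes and the tissues that could be carried over. Podocyte genes had 6 of 15 higher and 6 lower, with Nphs1 at log2 -1.24, and endothelial genes 4 of 20 higher and 7 lower, with Flt1 at log2 -0.92. Endoplasmic reticulum stress genes had 7 of 21 higher, with the asparagine synthetase gene Asns at log2 2.46, and 3 lower, with Herpud1 at log2 -2.09. Clock genes had 2 of 18 higher and 8 lower. Urothelium had 8 of 11 higher, with Krt14 at 10.9 ± 7.74 CPM after UUO from 4 counts in normal kidney, which limma-voom alone did not call (adjusted p = 0.0615, where the alternatives ran from 1.82e-07). Adipose tissue had 2 of 7 higher, adrenal gland 1 of 4 higher and 1 lower, pancreas and spleen 2 of 3 higher and 1 lower, muscle 2 of 7 higher and 4 lower, erythroid genes 0 of 7 higher and 2 lower, and male-biased genes 3 of 12 higher and 6 lower. The counts adjusted over the list alone differed in that stress genes had 6 higher and 2 lower, adipose tissue 1 higher and muscle 3 higher, and the other counts were the same. The median and the mean differed in sign for adipose tissue (-0.02 and 0.17, higher by camera) and erythroid genes (0.38 and -0.71, lower by camera). Of the 34 lists, 24 passed camera with the preset correlation, of which 0 passed with an estimated correlation, and 27 moved in one direction by fry.

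**Figure D2:**
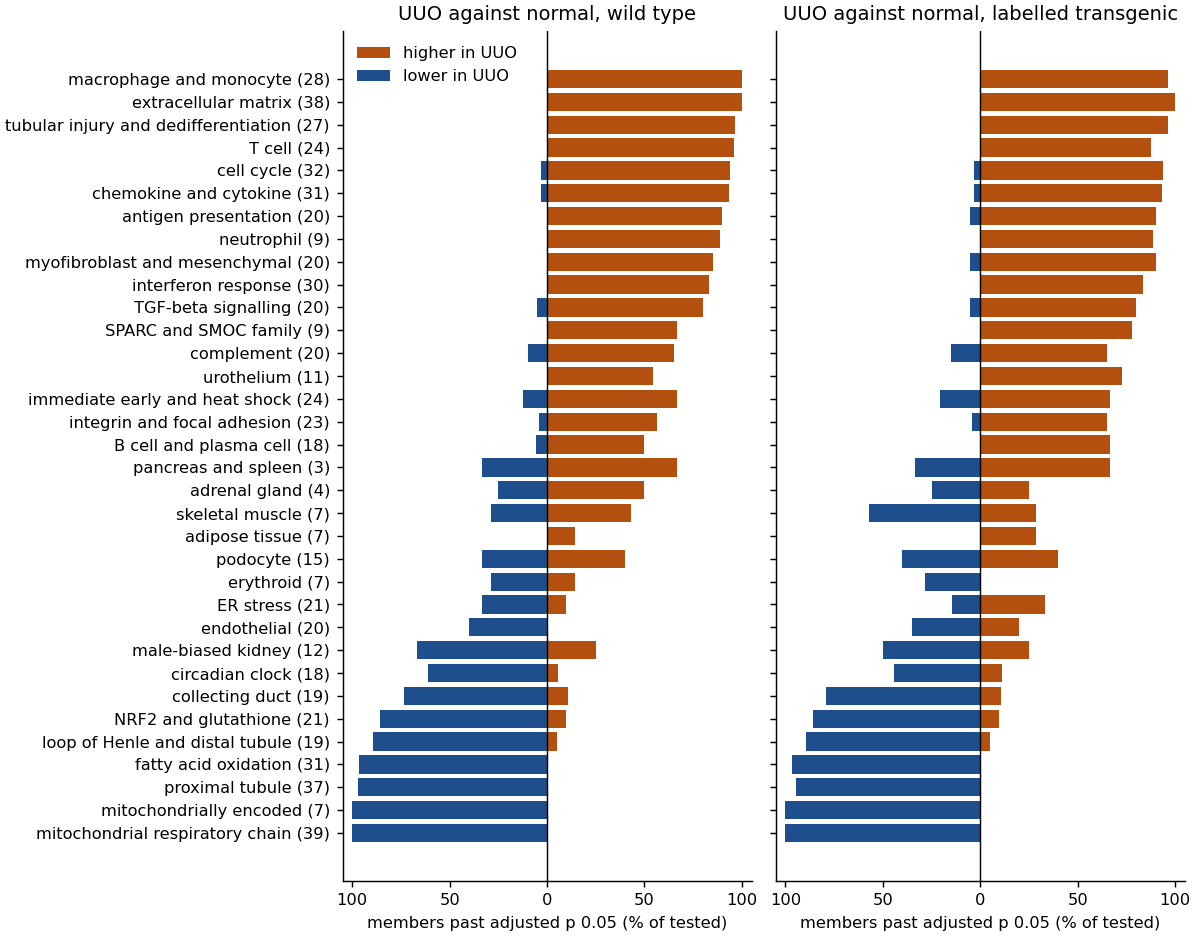
For each of the 34 lists, with the number of genes tested in brackets, the share of members past adjusted p 0.05 that were higher (right of 0) or lower (left of 0) after UUO, in percent of members tested, in wild-type (left panel) and labelled transgenic (right panel) kidney. All 38 extracellular matrix genes are higher and all 39 respiratory chain genes are lower in both panels.

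The responses of both genotype labels were close. Across 17926 genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.917, and the comparisons share no library. Among the changed genes, 4895 were higher in both, where 1818 would be shared by independent lists, 4660 were lower in both, where 1625 would be, and 5 went in opposite directions.

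**Figure D3:**
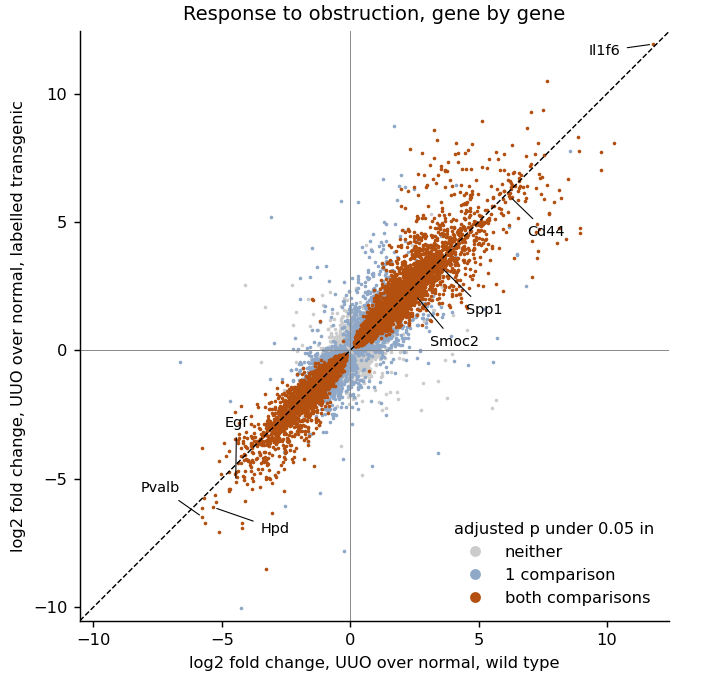
Log2 fold change of each of 17926 genes after UUO in wild-type (horizontal) and labelled transgenic (vertical) kidney, coloured by whether adjusted p was under 0.05 in both, in 1 or in neither comparison. The dashed line marks equal change. Points lie along it with a Pearson correlation of 0.917 across genes.

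In normal kidney, 5 genes changed between the genotype labels, and 4 of them were annotated pseudogenes. Gm10039 was at 72.4 ± 20.4 CPM (SD, n = 3) in the libraries labelled transgenic and 4.98 ± 0.420 CPM (SD, n = 3) in wild type (log2 3.86, edgeR adjusted p = 5.57e-05). The pseudogene Spr-ps1 was at 12.7 against 2.93 CPM and Gm5909 at 1.94 against 0.106 CPM. Gm11814 was at 0.0591 CPM, or 3 counts, against 4.11 CPM in wild type. Catspere2, related to a sperm calcium channel, was at 23.3 ± 6.68 against 2.85 ± 0.319 CPM (edgeR adjusted p = 0.0315). Reads of the pseudogenes can be shared with their parent genes, so their counts are uncertain. Those of Catspere2 are uncertain too, since they may be shared with Catspere1, an annotated pseudogene. Catspere1 was at 2.77 to 4.95 CPM in normal libraries labelled transgenic and at 0 in wild-type normal ones. Of the 5 changed genes, 4 also changed between the labels after UUO, in the same direction and in other libraries.

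No list member changed between the labels in normal kidney over all genes tested. Adjusted over the list alone, the cell cycle list had 2 higher and 1 lower, among them Ube2c at 6.22 against 2.77 CPM, the clock list had 2 lower, which were Clock (62.2 against 86.9 CPM) and Arntl (log2 -1.04), the complement list had 1 lower, C7 (1.80 against 5.58 CPM), and the NRF2 list 1 higher. The injury gene Havcr1 was at 304 ± 38.1 CPM in the libraries labelled transgenic and 53.7 ± 79.4 CPM in wild type (95% interval of the log2 difference 0.71 to 4.29, edgeR adjusted p = 0.292). Without wild-type normal library 1 it passed (log2 5.29, adjusted p = 2.25e-04, the lowest of its alternatives, which reached 0.529), and DESeq2 gave no adjusted p for it. After UUO, Havcr1 was at 525 to 868 CPM in the libraries labelled transgenic and 251 to 370 CPM in wild type, but was not among the list members that changed by edgeR. Col8a1 was at 6.14 against 10.7 CPM (adjusted p = 0.292) and the urothelial Krt15 at 0.176 against 1.94 CPM (adjusted p = 0.311). The mean log2 CPM of the adipose list was 1.69 to 2.37 in the libraries labelled transgenic, above each wild-type library, with 0 of its 7 genes changed by edgeR (camera adjusted p = 0.993 with an estimated correlation). None of the 34 lists passed camera with an estimated correlation or fry, and 0 had an unadjusted camera p under 0.05. With the preset correlation 1 list, extracellular matrix, was lower. With an estimated correlation the matrix, cell cycle, clock, complement and NRF2 lists had an adjusted p = 0.993. The median, the mean and camera's direction differed in sign for the injury, B cell, neutrophil, cell cycle, stress, adrenal and male-biased lists. DESeq2 called C7 (adjusted p = 0.00969), Ube2c (3.12e-04), Clock (0.00629) and Arntl (0.0239). The count of 5 became 174 with DESeq2, 9 with limma-voom, 12 without a filter and 8 with the compared groups alone, against 2299 genes at an unadjusted p under 0.05. Catspere2 lost its call with the replicate number as a block (adjusted p = 0.109) and without wild-type normal library 1 (adjusted p = 0.120), 2 (0.0764) or 3 (0.135), wild-type UUO library 4 (0.0508), transgenic normal library 4 (0.142) or transgenic UUO library 4 (0.0626), and Gm5909 without wild-type normal library 1 (0.0562). The count was 11 without wild-type normal library 2, 8 without wild-type normal library 3, 8 without wild-type UUO library 1 and 21 without transgenic normal library 1.

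After UUO, the kidneys labelled transgenic had higher levels of Timd2, Fst and Alpl and lower levels of S100g, Ednrb and Dnajb4 than wild type. Fst, at chromosome 13 from 114452290 to 114458951 on mm10, was at 76.1 ± 17.4 CPM (SD, n = 4) against 15.5 ± 8.21 CPM (SD, n = 4), a difference of 2.29 on the log2 scale (SE 0.29, edgeR adjusted p = 0.00332). Timd2, a cell surface receptor for ferritin, was at 5.64 ± 2.16 CPM (SD, n = 4) in wild type and 5.50-fold higher in the libraries labelled transgenic (log2 2.46, SE 0.31, edgeR adjusted p = 0.00332). Alpl, tissue-nonspecific alkaline phosphatase, was at 632 ± 164 against 236 ± 44.6 CPM, and the chaperone gene Dnajb4 at 41.1 against 65.7 CPM (log2 -0.68, SE 0.10). In all, 149 genes changed, with 100 higher and 49 lower, and 49 changed at least 2-fold.

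Higher in the libraries labelled transgenic were also Prodh2 of hydroxyproline breakdown (91.5 against 36.8 CPM), Cd300lf (12.7 against 5.81 CPM) and the small heat shock gene Hspb1 (133 against 61.9 CPM). Ighg1 (12.9 ± 15.4 against 0.629 ± 0.698 CPM) and Ighg2b (12.2 ± 9.59 against 0.716 ± 0.420 CPM) were higher with uncertain counts, since immunoglobulin constant genes are close copies. The log2 difference of Ighg1 was 4.32, 3.05 without transgenic UUO library 2 (adjusted p = 0.0708) and 5.44 without wild-type UUO library 3, and that of Ighg2b was 4.09, and 3.41 without transgenic UUO library 2. Lower were the calcium-binding S100g (25.3 against 67.0 CPM), Noct (18.5 against 40.2 CPM), the lysosomal channel gene Mcoln3 (13.9 against 27.8 CPM), Zfp758 and Cabcoco1. So were the basement membrane collagen gene Col4a3 (log2 -0.78, SE 0.16) and the endothelin receptor gene Ednrb (30.7 ± 2.33 against 52.1 ± 5.05 CPM).

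Few list members changed between the labels after UUO over all genes tested. They were Fst, Hspb1, the circadian repressor gene Cry2 (23.9 ± 3.20 against 11.5 ± 1.07 CPM, edgeR adjusted p = 0.0188), the calcium-binding chaperone gene Calr (1324 against 902 CPM) and Btg2, which was lower (55.8 against 80.3 CPM). Adjusted over the list alone, clock genes had 9 of 18 higher, with Dbp at 24.5 against 6.48 CPM and Per2 at 27.3 against 14.2 CPM, and 4 lower. On the same basis, the collecting duct list had 7 of 19 lower, with the sodium channel gene Scnn1g at 38.1 against 52.8 CPM, endoplasmic reticulum stress genes 6 of 21 higher, with Hsp90b1 at 690 against 483 CPM, and neutrophil genes 3 of 9 higher, with Ltf at 1.31 against 0.203 CPM. Camera with an estimated correlation gave adjusted p = 0.446 for the clock, collecting duct and neutrophil lists and 0.854 for the stress list. Among the other lists, and adjusted over the list alone, immediate early genes had 1 higher and 3 lower, the SPARC, SMOC and follistatin-domain list and complement 1 higher and 2 lower each (adjusted p = 0.991 for all 3 with an estimated correlation), and the rest at most 2 in either direction. Of 38 matrix genes and 20 myofibroblast genes 0 changed by edgeR (camera adjusted p = 0.991 for both), with Acta2 at 218 ± 45.5 against 252 ± 52.0 CPM (edgeR adjusted p = 0.668), Timp1 at 161 against 86.9 CPM (adjusted p = 0.160) and Fbln2 at 54.0 against 28.0 CPM (adjusted p = 0.0972). Timp1 passed with the replicate number as a block (adjusted p = 0.0452, where its alternatives reached 0.352), and Fbln2 with DESeq2 (0.0121) and without transgenic UUO library 4 (0.0354), where its alternatives reached 0.228. Tgfb1 was at 97.5 against 67.1 CPM (adjusted p = 0.0805), Spp1 at 14957 against 23013 CPM (adjusted p = 0.0830), the potassium channel gene Kcnj1 at 88.5 against 154 CPM (adjusted p = 0.0519) and the macrophage gene Gpnmb at 11.5 against 3.10 CPM (adjusted p = 0.0602). The plasma cell genes Igkc (125 ± 67.5 against 21.6 ± 12.4 CPM) and Jchain (20.6 against 3.70 CPM) had edgeR adjusted p of 0.165 and 0.145. The mean log2 CPM of the adipose list was 1.81 to 2.74 in the libraries labelled transgenic and 1.39 to 1.53 in wild type except for library 1 at 2.61, with 0 of its 7 genes changed (camera adjusted p = 0.561 with an estimated correlation). The median, the mean and camera's direction differed in sign for the myofibroblast, fatty acid oxidation and T cell lists. By list, 0 of 34 passed camera with an estimated correlation, 3 had an unadjusted p under 0.05, 9 passed with the preset correlation, 0 passed fry and 7 passed its mixed form.

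The count of 149 genes depended on the fit and on single libraries. It was 746 with DESeq2, 232 with limma-voom, 69 with the replicate number as a block and 39 with only the compared groups, against 2716 genes at an unadjusted p under 0.05. It was 64, 70 and 63 without wild-type UUO library 1, 3 or 4, and 71, 29 and 45 without transgenic UUO library 1, 2 or 3. Of the 19 changed genes named here for this comparison, Timd2, Fst, Alpl and Dnajb4 passed in every alternative, and the other 15 lost their call in at least 1. S100g, Btg2 and Ighg2b lost it only with the compared groups alone. Cry2 lost it without wild-type UUO library 1 (adjusted p = 0.0521) or 4 (0.0504) or transgenic UUO library 3 (0.0532), and Ednrb without wild-type UUO library 1 (0.0625) or 4 (0.0688) or transgenic UUO library 1 (0.0667), 2 (0.0686) or 3 (0.0609). Prodh2, Cd300lf, Hspb1, Calr, Noct, Mcoln3, Zfp758, Cabcoco1, Col4a3 and Ighg1 each lost it without transgenic UUO library 2 (0.0556 to 0.148) or 3 (0.0544 to 0.113) and without at least 3 others. All of these but Noct and Ighg1 also lost it with the replicate number as a block (0.0610 to 0.0757). Genes short of the threshold passed it without single libraries too. They were Dbp without wild-type normal library 1 (0.0486) or 2 (0.0358), Per2 without wild-type normal library 2 (0.0479), Scnn1g and Kcnj1 without wild-type UUO library 3 (0.0493) and 1 (0.0439) respectively, Ltf without transgenic UUO library 1 (0.0497), and Fbln2 (0.0354) and Gpnmb (0.0396) without transgenic UUO library 4. DESeq2 called these genes as well as Hsp90b1, Tgfb1 and Spp1. Kcnj1 also passed with upper-quartile scaling (0.0423), no filter (0.0329), the stricter filter (0.0473) and limma-voom (0.0436). Dbp (0.0442) and Gpnmb (0.0375) passed without a filter, and Hsp90b1 with limma-voom (0.0465). Wild-type UUO library 3 also stood apart in composition, with 95.8% of counts in protein-coding genes, where the nearest other library of its group had 98.3%.

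**Figure D4:**
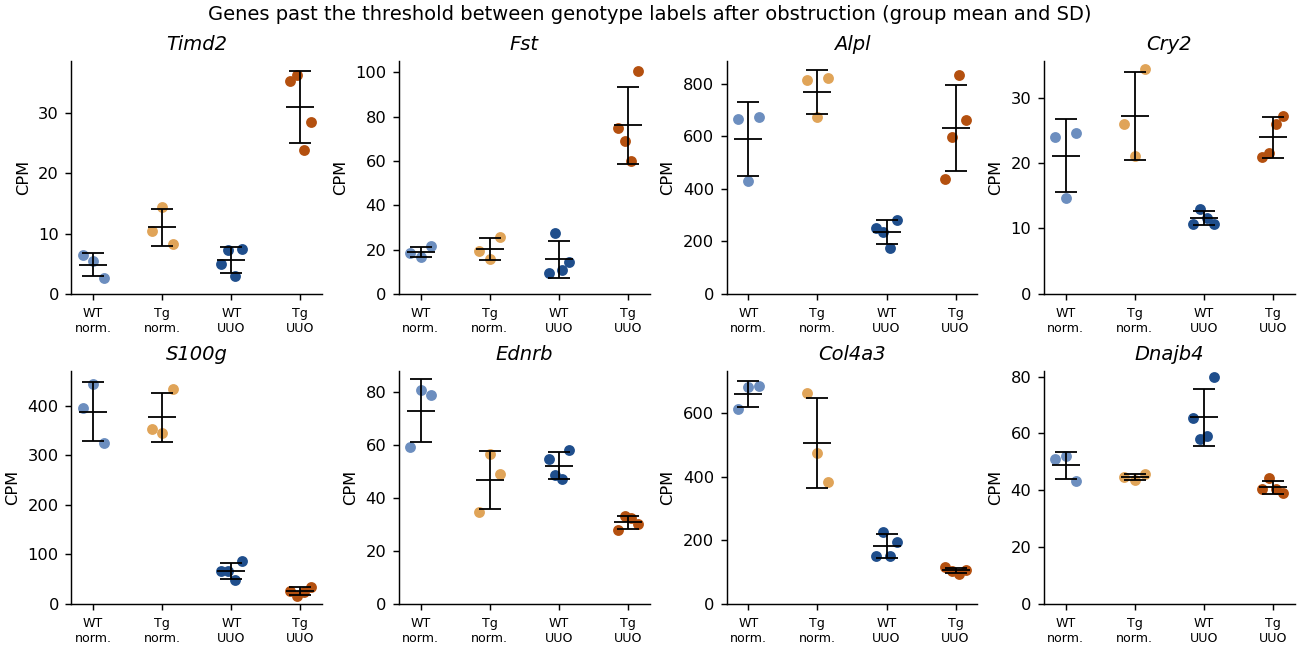
Levels of 8 genes in each library, in CPM on the vertical axes, in wild-type (WT) and labelled transgenic (Tg) kidney, normal and after UUO. Points are libraries and bars are the group mean and SD. Fst is at 76.1 CPM in labelled transgenic UUO kidney against 15.5 CPM in wild type, and Ednrb at 30.7 against 52.1 CPM.

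The interaction asked whether the response to obstruction differed between the genotype labels. No gene passed in edgeR's test (lowest adjusted p = 0.0871), while 1154 genes had an unadjusted p under 0.05. DESeq2 called 25, limma-voom called 0, and edgeR called 1 without a filter and 1 with the block. The count was 1 without wild-type normal library 1, without wild-type UUO library 1, 2 or 4 or without transgenic normal library 4, and 2 without transgenic normal library 1. The response of Smoc2 differed by -0.39 on the log2 scale (95% interval -1.46 to 0.68, edgeR adjusted p = 0.908), and by -1.04 without wild-type normal library 3 and -0.07 without wild-type normal library 1. Fst had a difference of response of 2.20 (95% interval 1.26 to 3.14, edgeR adjusted p = 0.483), and it passed without wild-type UUO library 2 (2.63, adjusted p = 0.0191) and with DESeq2 (adjusted p = 0.00463), where its alternatives reached 0.679. Adjusted over the list alone, Fst passed in the SPARC, SMOC and follistatin-domain list, complement had 2 higher and 1 lower, with the receptor gene C3ar1 at 1.38, cell cycle had 1 higher, the spindle gene Tpx2 at 0.96, and immediate early genes had 1 lower, Atf3 at -1.83. Over all genes, DESeq2 called C3ar1 (adjusted p = 0.0165) and Atf3 (adjusted p = 0.0448). With an estimated correlation, camera gave adjusted p = 0.992 for the SPARC, SMOC and follistatin-domain list and 0.954 for the other 3 lists. Leading members of the matrix (Col8a1 at 1.24, Tnc at 1.46), TGF-beta (Tgfb1 at 0.59) and clock lists (Per1 at -1.60) had adjusted p of 0.570 or more over all genes. The median, the mean and camera's direction differed in sign for the TGF-beta, injury, macrophage, adrenal and erythroid lists. Of the 34 lists 0 passed camera with an estimated correlation, 0 had an unadjusted p under 0.05, 0 passed fry and 10 passed with the preset correlation.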

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

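The tests of the wild-type obstruction count over other splits, of mislabelled samples, of the transcripts with a gap between libraries and of the clock genes were chosen after the result was seen. In groups of 4, a library counts as apart when its gap to the nearest other, divided by the group's range, exceeds Dixon's 95% critical value. This picked out 16 of 302 groups (5.3%), close to the 1 in 20 that chance gives.

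In wild-type UUO, library 3 had 95.8% of its counts in protein-coding genes, where the nearest other had 98.3%. Of each library's total scaled to CPM, it also had 15186 for the ribosomal RNA gene CT010467.1 against at most 4092 elsewhere, and 173 for Rn7sk against at most 12.2. Library 4 had the highest mean of the interferon list, 5.38 against 4.41 on the log2 CPM scale, and library 1 the highest mean of the adipose list, 2.61 against 1.53. Arhgap36 was at 34.3 CPM in library 1, where the nearest other was at 23.4 CPM. In library 4, Ly6f was at 3.98 CPM (nearest 1.19), Gatm at 282 CPM (nearest 154), Fgb at 26.8 CPM (nearest 2.77) and Tnc at 114 CPM (nearest 167). Catspere2 was at 6.22 CPM in library 3 (nearest 2.73).

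In transgenic UUO, Smoc2 was at 124 CPM in library 1, where the nearest other was at 89.9 CPM, and in the same library Ccl7 was at 9.03 CPM (nearest 7.14) and Zfp758 at 8.90 CPM (nearest 7.09). In library 2, Catspere2 was at 8.76 CPM (nearest 4.02) and Ighg1 at 35.7 CPM (nearest 8.45). Tagln was at 249 CPM in library 4 (nearest 310) and Hsp90b1 at 563 CPM in library 3 (nearest 720).

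Smoc2 was not higher in the libraries labelled transgenic. If the transgene raised Smoc2 counts, a single wrong label or a swapped pair within 1 state would leave at least 3 of the 7 libraries labelled transgenic above every wild-type library of their state, and 0 were. Scaling was not decided, since the 4 scalings tried moved the difference after UUO only between -0.63 and -0.60 on the log2 scale. An exchange of all genotype labels could not be decided, since 5 of 7 libraries labelled wild type, all 4 after UUO among them, lay above every library labelled transgenic of their state, and 2 normal ones did not. A transgene whose transcript is not counted at Smoc2 was not tested and stays open, as may a transgene without effect on whole-kidney RNA.

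Over other splits of the same libraries, only the real split gave as many genes for wild-type UUO against normal (1 of 35 splits as large, real 10950, highest other 6261) and for transgenic UUO against normal (1 of 35, real 11264, highest other 5774). The same held for the genotype labels after UUO (1 of 35, real 149, highest other 47). A share of 1 in 35 is the smallest these splits can give, so chance is made unlikely at that level and is not excluded. The other splits also mix the real groups, which widens the spread within groups and lowers their counts. In normal kidney the 10 splits are too few for a share under 0.05, with 5 genes in the real split and 7 in the highest other. For the interaction the real count was 0, so that all 100 drawn splits necessarily gave as many genes (highest other 3), and the splits decide nothing.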

How the results depend on the processing

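All alternatives reported here were planned, and none was chosen after the result was seen. Both obstruction counts stayed within 1.5 times under each of them, at 9664 to 11240 genes in wild type and 9891 to 11584 in labelled transgenic kidney, and at 9879 to 11073 and 10180 to 11458 with 1 library left out. Of 1034 and 924 values of the genes named there, all but 1 each kept direction and side of the threshold; the exceptions were Krt14 in limma-voom. No value of a named gene other than Smoc2 changed sign. The count between labels in normal kidney was 12 without a filter, 174 with DESeq2, 9 with limma-voom and 8 with the compared groups alone, and 4 to 21 with 1 library left out. After UUO it was 746 with DESeq2, 232 with limma-voom and 39 with the compared groups alone (32 shared with the 149), and 29 to 158 with 1 library left out. With the replicate block it was 69, of which 62 were shared. For the interaction it was 1 without a filter, 25 with DESeq2 and 1 with the block, and 0 to 2 with 1 library left out. The cause was not tested, except that leaving out libraries or groups leaves fewer samples. Replicate numbers gave no sign of pairing: over 18 pairs with the same number the median correlation of deviations was 0.008, 1 exceeded 0.1, and 4 of 14 libraries correlated best with their own number. Most of these pairs cross genotypes. Those of a normal and a UUO library of the same genotype ran from -0.0898 to 0.0709 and are too few to exclude pairing. Smoc2 in normal kidney ran from -0.55 to 0.43 with 1 library left out, and its sign reversed without wild-type normal library 3 (0.43) and transgenic normal library 4 (0.11). With the preset correlation, 24, 24, 1, 9 and 10 lists passed in the 5 comparisons. With 1 library left out, 0 to 1 lists passed in each obstruction comparison, the 1 without transgenic UUO library 2 or 4, and 0 in the others. Of 418 values of the 19 changed genes named between labels after UUO, 119 fell short of the threshold. No value could be had for Gm5909 and Ltf with the stricter filter, Krt15 and Ltf with the compared groups alone. DESeq2 gave Havcr1 in normal kidney a log2 difference of 2.498 without an adjusted p. Small changes were the least detectable with these groups and library sizes, and depth was not varied. In simulation, 1.5-fold changes between labels after UUO were found in 36.5% of cases.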

Other observations

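The tests of transcripts with a gap between libraries and of clock genes were chosen after the result was seen, as were the limits that define such a gap.

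Of the 13 protein-coding genes of the mitochondrial genome, 6 that lie side by side had almost no counts. From mt-Co2 at position 7013 to the end of mt-Nd4l at 10173, mt-Co2, mt-Atp8, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l had 4, 0, 4, 2, 0 and 0 counts over all 14 libraries together. Their neighbours mt-Co1 and mt-Nd4 had 5356007 and 2001308 counts.

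Of the clock genes sorted by phase, Cry2 alone changed between the genotype labels after UUO (edgeR adjusted p = 0.0188, and 0.0521 without wild-type UUO library 1, 0.0504 without wild-type UUO library 4 and 0.0532 without transgenic UUO library 3), and the clock list had a camera adjusted p = 0.446 with an estimated correlation. The 11 genes that peak with Dbp had a median difference of 0.84 on the log2 scale, labelled transgenic over wild type, with 10 above 0, and the 5 that peak with Arntl, of which 0 changed by edgeR, had a median of -0.32, with 1 above 0. That median of -0.32 argues against scaling or depth, which would move all clock genes alike. A smaller overall response to obstruction is argued against too. Over the genes changed in wild type, the libraries labelled transgenic lay at 1.004 times the wild-type position along the wild-type response. That position rests on all these genes, not on the clock genes alone. The clock index below differed between the labels by 1.13 both in normal kidney and after UUO, and no gene passed edgeR's interaction test. The index varied from -0.02 to 2.02 among wild-type normal libraries, so a smaller response of the clock genes alone is not decided. Collection of the labels at different times of day may account for the pattern but cannot be told apart from an effect of genotype, since no collection time is given. The index of Dbp-phase over Arntl-phase genes was 1.13 higher after UUO (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 libraries allow) and 1.13 higher in normal kidney (exact two-sided permutation p = 0.200, where the smallest possible is 0.1).

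Some transcripts had a wide gap between a high and a low set of libraries that parted libraries of the same group. The low set need not lack the transcript, as for Havcr1 at 4.13 and 11.6 CPM and H2-Eb1 at 3.07 and 3.82 CPM in their low libraries. With a gap of at least 2.5 on the log2 scale, a pseudocount of 0.1 CPM and a highest level above 2 CPM, 58 genes on chromosomes 1 to 19 and X were of this kind, and 25 of them (43.1%) were pseudogenes, against 3.36% of all genes tested (odds ratio 22.7, Fisher's exact two-sided p = 5.47e-22). Another 7 were non-coding RNAs, Rn7sk and Rmrp among them, that were high in wild-type UUO library 3 alone. Most of the 58 genes were high in libraries of both genotype labels, but some followed the label in part. Catspere1 was high in all 7 libraries labelled transgenic and in wild-type UUO library 3. Got2-ps1 and Gm10320 were high in 5 libraries each, all labelled transgenic, and Gm7244 in 4, all wild type. Whether the labels differ in strain variants was not tested.

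Reads shed by a changing parent gene are argued against for the 5 pseudogenes with a named parent tested. Their parents differed by a median size of 0.164 on the log2 scale. The other pseudogenes, and reads shared with a parent at a constant level, were not tested. Segregating strain variants could give such a pattern and would make neighbouring genes share their high or low state. By the measure used, neighbours did not share their state more often. Over 15 pairs within 5 Mb, a mean of 64.8% of libraries agreed, in the same or the opposite sense, whichever was more. The mean over all pairs was 66.8% (permutation p = 0.751, 10000 shuffles). Each gene was split only at its widest gap, so sharing at another level was not tested. On chromosome 17, H2-Eb1 was at 699 CPM, Btnl2 at 0.27 CPM and Gm8909 at 1.35 CPM in wild-type UUO library 2. The rest of that group was at 22.9 to 36.6, 5.85 to 10.2 and 53.2 to 92.9 CPM. Transgenic UUO library 1 was at 23.4, 7.81 and 49.6 CPM. Transgenic UUO libraries 2 to 4 were at 287 to 483, 2.02 to 5.11 and 25.6 to 38.8 CPM. In transgenic normal library 3, H2-Eb1 was at 78.2 and Gm8909 at 1.28 CPM. The other normal libraries had 3.07 to 40.3 and 9.23 to 19.6 CPM, and Btnl2 was at most 0.27 CPM in every normal library. Strain variants stay open because the pairs are few and only the widest gap of each gene was used.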
